A study of Mus musculus with 12 samples.

How the data were processed

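T cell receptor (TCR) transcripts were sequenced from CD8+ T cells that bind an Rpl18 tetramer, sorted from the tumor or the tumor-draining lymph node (TDLN) of mice on day 10 after injection of MC38 tumor cells. The 12 libraries fall into 4 groups of 3 by genotype (WT, or KO for mice with a CD8-specific TrIP knockout) and tissue. Groups and numbers were taken from the labels. The WT TDLN libraries carry numbers 1, 3 and 4 and the WT tumor libraries numbers 2, 3 and 4. WT tumor 2 is numbered 1 in the deposited tables and was matched by its library name. The knockout could not be checked, since no expression values were analysed here.

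Per the labels' protocols, libraries were made from polyA RNA with TCR-specific primers. No molecular identifiers are described, so a count is a count of reads, and intervals and floors cover counting error only. The labels name the genome build GRCm39. Per the file headers, the row tables are TRUST4 reports, whose version is not given in the sources used here. Each row of the TRA table holds the deposited count of reads of 1 TRA CDR3 rearrangement in 1 library, for all 12 libraries. Beside it the authors give a fraction of the TRA total of the library. A further table of all chains holds counts and fractions for 8 of the 12 libraries. Of its 88 V segment names, 28 were found among mouse gene symbols of GRCm38.p6, and they hold 25.8% of its reads. Of the V names of TRA, 99 of 100 were found, with 99.9997% of the reads. The V and J segments of TRB were therefore not analysed here, and TRB CDR3 sequences were used without them. A sheet of metrics gives, per the file headers, counts of different CDR3 sequences and the share of a chain taken by the top clone and the top 5 and 10 clones. The deposited score columns of that sheet hold the number of different TRA sequences and the share of the top TRB clone, and how the authors computed the sheet is not stated. A deposited matrix gives the count of TRB sequences that each pair of libraries shares. The matching TRA matrix was not used, because its header is shifted against its rows, and TRA sharing was computed from the TRA table. The run log notes 4 libraries as timed out (WT TDLN 1, WT TDLN 3, KO TDLN 1 and KO TDLN 2), all of them from TDLN.

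Of 731688 TRA reads in 10521 rows, 85.3% were kept as productive. Rows called out of frame, or with a stop or an unread base, were left out. TRAJ7 rows were treated apart: 90.0% of the 561 TRAJ7 rows were called out of frame as deposited, against 20.9% of the rows of other TRAJ segments. Among other segments of 50 rows or more the highest share was 70.8%, for TRAJ34. The CDR3 of TRAJ7 rows was taken to end 1 base early, so TRAJ7 rows with a length of 2 more than a multiple of 3 were translated with that base restored. This moved 6.12% of all TRA reads into frame. This rule was chosen after the values were seen, and the deposited frame is among the alternatives. A clonotype is 1 CDR3 nucleotide sequence with its V and J segment, with the near-identical duplicated copies of V segments pooled. The tables held 6563 TRA clonotypes over all libraries.

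Productive TRA reads ranged from 15828 to 94872 per library, and assembled reads of all chains from 106344 to 654080. The number of clonotypes was rarefied to 15828 reads, the depth of the smallest library. Clonality is 1 minus the Shannon entropy divided by the logarithm of the number of clonotypes. The top 10 share is the percent of productive reads in the 10 largest clonotypes. CDR3 length is the mean number of amino acids, weighted by reads. For TRB, the number of sequences and the top 10 share are the deposited values, and clonality and length came from the rows of the tumor libraries. Overlap of TRA between libraries is the Morisita-Horn index, from 0 to 1, and overlap of TRB is the Jaccard index in percent. Sequences counted as found in several mice, and clonotypes shared between mice, were taken by the letter in the library names. A letter is shared by 1 TDLN and 1 tumor library, and whether it marks a mouse was not established.

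Single values were compared with exact two-sided permutation tests over libraries. These tests, the SDs and the segment tests treat libraries as independent, which does not hold where libraries share clonotypes. With 3 libraries against 3 the smallest possible p is 0.1. Tumor and TDLN over both genotypes were compared by exact permutation within genotype (400 assignments, smallest p 0.005). Overlap of same-numbered against different-numbered pairs had an exact one-sided test. The 35 tests of single values were adjusted together by the Benjamini-Hochberg method. The difference between genotypes of tumor minus TDLN is given with no test. TRAV and TRAJ segments were tested on read counts with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with all 4 groups in the fit and the library total as the scale, at an adjusted p threshold of 0.05. Segments with under 10 reads in all, or under 0.1% in every library, were left out, which left 47 TRAV and 43 TRAJ segments. DESeq2 1.42.0 and limma 3.58.1 were alternatives. Shares of single libraries carry 95% Wilson intervals, and a share of 0 a floor of 3 counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

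The segment test was tested on simulated counts with the observed means, totals and spread, 20 segments changed per draw and 20 draws. For tumor minus TDLN over both genotypes it recovered 46.75% of TRAV and 19.75% of TRAJ segments changed 64-fold, and 0.75% and 0.5% of those changed 8-fold. For KO minus WT in tumor it recovered 0.25% of TRAV and 0.25% of TRAJ segments changed 64-fold.

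The rule for the segments and clonotypes named was set before the data were examined: called segments with the smallest p, up to 10 per kind and comparison, filled up to 5 per kind with the segments of the largest mean share; the 3 clonotypes with the largest mean share in each group; and the 10 CDR3 sequences of each chain found in the most mice. Markers of other T cells were set then too: TRAV11 with TRAJ18 for invariant NKT cells, TRAV1 with TRAJ33 for MAIT cells and any gamma or delta chain. Since the primers amplify alpha and beta chains, the check for gamma and delta chains is void. Alternatives were the definition of a clonotype, low counts, depth, other indices and numbers of top clones, other tools and scales for segments, leaving out each library, and the replicate number as a block. Chosen after the values were seen were merging of rare neighbours, leaving out clonotypes shared between mice, the deposited TRAJ7 frame, leaving out WT tumor 3 and KO tumor 3, the top 5 share of TRB, the TRB top 10 share from the entries of the tumor libraries, the share of the smaller library for TRB overlap, leaving KO tumor 2 and KO tumor 3 unpaired, and segment counts from all deposited entries.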

Results

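The receptor repertoires of CD8+ T cells that bind an Rpl18 tetramer were measured in MC38 tumors, a transplanted mouse colon carcinoma line, and in their draining lymph nodes on day 10. TrIP is a membrane protein of T cells, and the KO mice lacked it in CD8+ cells. The 4 groups of 3 libraries were WT TDLN, WT tumor, KO TDLN and KO tumor. The design sets WT against KO within a tissue, and tumor against TDLN within a genotype. Assembled reads ranged from 106344 (WT TDLN 4) to 654080 (WT TDLN 1). Productive TRA reads ranged from 15828 (WT TDLN 4) to 94872 (WT tumor 2), with a median of 48625.5. Of the TRA clonotypes, 65.8% were seen as a single read in their library. Reads outside the 100 largest TRA clonotypes made up 2.04% ± 1.23 of WT TDLN, 0.731% ± 0.329 of WT tumor, 3.05% ± 0.668 of KO TDLN and 0.997% ± 0.159 of KO tumor libraries (SD, n = 3 each). No read had the invariant NKT or the MAIT rearrangement in any of the 12 libraries, which allows shares of up to 0.00316% to 0.0190% of productive TRA reads, depending on the library.

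The number of TRA clonotypes at equal depth was 318.3 ± 88.8 in WT TDLN, 190.7 ± 53.9 in WT tumor, 404.6 ± 35.3 in KO TDLN and 241.9 ± 20.9 in KO tumor (SD, n = 3 each). Variants 1 base from a clonotype at least 100 times more abundant made up 33.3% to 54.6% of the listed clonotypes in TDLN libraries. In tumor libraries they made up 51.1% to 67.4%, so the numbers may include sequence errors. Over both genotypes tumor libraries held fewer clonotypes, with a tumor minus TDLN difference of -145.1 (exact two-sided permutation p = 0.01). Adjusted over the 35 tests of single values the p was 0.35, so the difference did not pass the correction. By the number as listed the difference was -242.7 (exact p = 0.085), and with clonotypes under 0.01% left out it was -82.8 (exact p = 0.005). Within WT the difference was -127.6 (exact p = 0.2) and within KO it was -162.7 (exact p = 0.1, the smallest possible with 3 against 3). KO minus WT was 86.3 in TDLN (exact p = 0.2; 38.2 without WT TDLN 4) and 51.3 in tumor (exact p = 0.3; 21.6 without WT tumor 2). With the TRAJ7 frame as deposited these were 19.1 and 19.6, and the tumor value was -72.0 by the number as listed. Of the 6 TDLN libraries, 4 came from runs noted as timed out and none of the 6 tumor libraries did, so the note and the tissue are partly confounded.

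**Figure D1:**
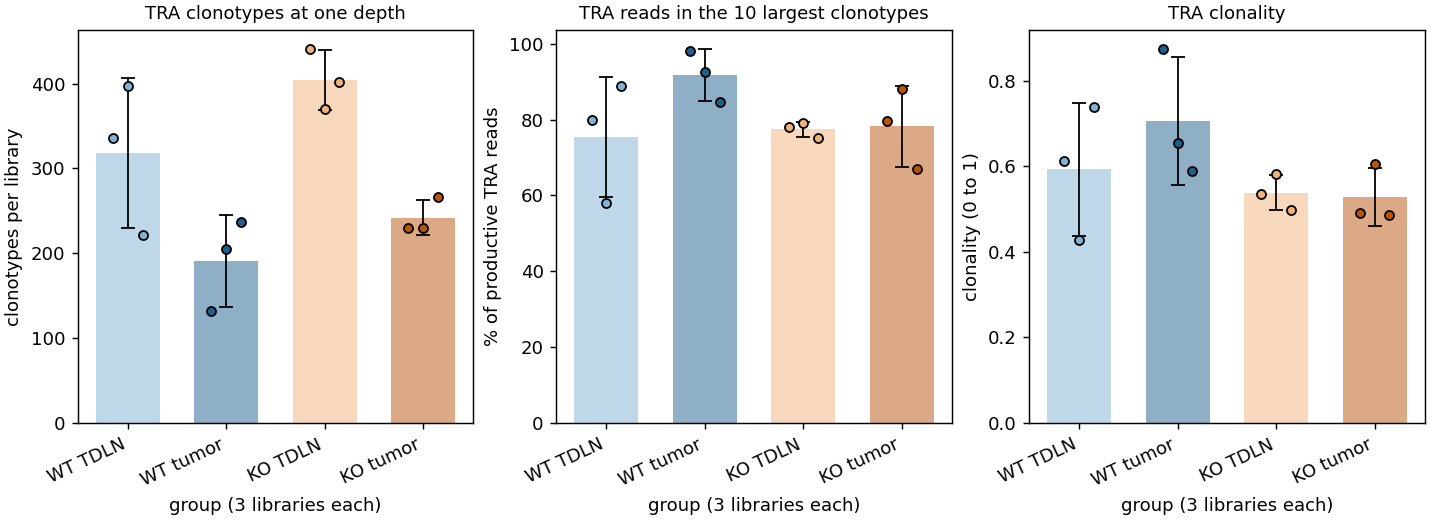
TRA clonotypes per library at equal depth, percent of productive TRA reads in the 10 largest clonotypes, and clonality, for the 4 groups. Points are libraries, bars are means and whiskers are 1 SD (n = 3). Clonotype numbers in KO tumor, 241.9 on average, lie below all 3 KO TDLN libraries.

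TRA clonality was 0.593 ± 0.156 in WT TDLN, 0.706 ± 0.150 in WT tumor, 0.539 ± 0.0417 in KO TDLN and 0.529 ± 0.0677 in KO tumor (SD, n = 3 each). KO minus WT was -0.177 in tumor (exact two-sided p = 0.2) and -0.0545 in TDLN (exact p = 0.6). The tumor difference was -0.0928 without WT tumor 2 and -0.0493 with clonotypes shared between mice left out (exact p = 0.3 each). The TDLN difference was 0.102 with the TRAJ7 frame as deposited (exact p = 0.5), 0.0184 without WT TDLN 4 (exact p = 0.9) and -0.137 without WT TDLN 3 (exact p = 0.1). The 10 largest TRA clonotypes took 75.5% ± 15.9 of WT TDLN, 91.9% ± 6.82 of WT tumor, 77.4% ± 2.05 of KO TDLN and 78.2% ± 10.7 of KO tumor reads. In tumor the KO minus WT difference was -13.6 points (exact p = 0.2). It was -7.95 without KO tumor 3 (exact p = 0.3), -7.53 without WT tumor 3 and KO tumor 3 (exact p = 0.667) and -3.00 with clonotypes shared between mice left out (exact p = 0.8). The top 10 TRB share of the authors' metrics was 79.9% ± 15.4 in WT TDLN, 90.5% ± 7.24 in WT tumor, 80.3% ± 7.15 in KO TDLN and 74.1% ± 9.31 in KO tumor. KO minus WT in tumor was -16.4 points (exact p = 0.1, the smallest possible, adjusted p 0.583). From the TRB entries of the tumor libraries the top 10 share was 94.2% ± 3.02 in WT and 86.6% ± 7.94 in KO, a difference of -7.66 points (exact p = 0.3). The depth behind the deposited shares is not stated. The share of the top TRB clone differs from that of the entries in every library with both. It was 12.5% in the metrics and 40.5% in the entries for KO tumor 2, 89.9% and 35.5% for WT TDLN 4, and 23.5% and 21.4% for KO TDLN 3. TRB clonality in tumor was 0.701 ± 0.0345 in WT and 0.627 ± 0.0545 in KO (difference -0.0738, exact p = 0.2; -0.0481 without KO tumor 3). Different TRB sequences numbered 2243 ± 174 in WT TDLN, 2068 ± 482 in WT tumor, 2465 ± 640 in KO TDLN and 2648 ± 538 in KO tumor, with exact p from 0.2 to 0.99 over the comparisons. Mean TRA CDR3 length was 14.67 ± 0.240, 14.27 ± 0.546, 14.48 ± 0.276 and 14.68 ± 0.157 amino acids in WT TDLN, WT tumor, KO TDLN and KO tumor, with exact p from 0.3 to 0.5. Mean TRB CDR3 length in tumor was 14.86 ± 0.378 in WT and 14.52 ± 0.390 in KO (exact p = 0.4). None of the comparisons of 3 against 3 libraries could reach a p under 0.1. The difference between genotypes of tumor minus TDLN was tested only with the replicate number as a block, and those p values are not given here. It was -35.1 for TRA clonotypes, -0.123 for TRA clonality, -15.5 points for the TRA and -16.8 points for the TRB top 10 share, and 358.3 for TRB sequences. With single libraries left out these ranged from -74.4 to 13.07, from -0.196 to -0.0382, from -22.2 to -6.75, from -23.9 to -8.68 and from 65.5 to 725.7 in that order.

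Segment usage varied widely between libraries of a group. The V segments with the largest mean share over the 12 libraries were TRAV16 (16.3% ± 13.3), TRAV14-2 (12.5% ± 24.1), TRAV3-3 (10.7% ± 12.9), TRAV7-4 (10.5% ± 16.4) and TRAV6-7 (8.67% ± 22.9). The leading J segments were TRAJ42 (19.8% ± 20.5), TRAJ7 (12.03% ± 22.4), TRAJ22 (11.8% ± 24.8), TRAJ17 (8.17% ± 13.8) and TRAJ30 (7.24% ± 13.3) (SD, n = 12). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 47 TRAV and 0 of 43 TRAJ segments differed between KO and WT in either tissue. At an unadjusted p under 0.05 there were 1 TRAV and 1 TRAJ segments in TDLN and 11 and 10 in tumor. DESeq2 called 1 TRAV and 0 TRAJ segments in TDLN and 2 and 3 in tumor, and limma called 0 and 0 in TDLN and 0 and 1 in tumor with 0.1% added, and 0 throughout with 1% added. On counts simulated for the tumor comparison the edgeR test recovered 0.25% of TRAV and 0.25% of TRAJ segments changed 64-fold. It thus missed nearly all changes even of that size, so the absence of calls says little about segment usage. The TDLN comparison was not simulated.

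Tumor minus TDLN over both genotypes gave 12 lower and 0 higher TRAV segments, and 8 lower and 0 higher TRAJ segments. Most are minor segments of the TDLN libraries. TRAJ43 took 0.869% ± 1.09 of TDLN reads, was found in 6 of 6 TDLN libraries and had no read in the 6 tumor libraries together, which allows a share of up to 0.000899% (edgeR adjusted p 0.00285). TRAV9-3 took 0.318% ± 0.345 of TDLN reads in 6 of 6 libraries and also had no tumor read (adjusted p 0.00621). TRAJ13 had no tumor read either and was found in 5 of 6 TDLN libraries at 0.460% ± 0.453 (adjusted p 0.00285). TRAJ26 fell from 0.447% ± 0.264 to 1 read in the tumor libraries (adjusted p 0.00489). Adjusted p of TRAJ56, TRAJ57, TRAJ16, TRAJ44 and TRAJ40 ranged from 0.00860 to 0.0431. Those of TRAV19, TRAV10, TRAV6-4, TRAV6-2, TRAV8-1, TRAV9-2, TRAV6-3, TRAV15-1, TRAV17, TRAV6-7 and TRAV8-2 ranged from 0.00888 to 0.0277. Of these, TRAV6-7 took more of KO tumor (4.21% ± 3.40) than of KO TDLN reads (1.80% ± 2.55), so its call rests on WT. The count of TRAV segments fell to 0 with limma and to 2 with TMM scaling, while DESeq2 called 6 lower and 4 higher. Without WT tumor 2 it was 3, without KO tumor 1 it was 5 and without KO tumor 2 it was 4. With clonotypes shared between mice left out it was 1. With the replicate number as a block 0 TRAV and 0 TRAJ segments were called, though the labels do not say that a number marks a mouse. For TRAJ the count was 2 and 0 with limma (0.1% and 1% added), 7 with shared clonotypes left out, 5 without KO TDLN 2 and 5 without KO tumor 1. Within WT alone 1 TRAV segment was called, TRAV6-7, at 28.6% ± 45.3 of TDLN and 0.0161% ± 0.0142 of tumor reads (adjusted p 0.0414). This segment took 80.8% of reads in WT TDLN 4. Leaving out WT TDLN 3, WT TDLN 4 or any of the WT tumor libraries ended the call, with 0 segments each. Within KO no segment was called (edgeR, 13 TRAV and 8 TRAJ segments at an unadjusted p under 0.05, 8 and 7 called by DESeq2, 4 and 0 by limma with 0.1% added). In WT 0 TRAJ segments were called (11 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma).

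TRAJ segments were also pooled into 3 sets by their numbers, a grouping set before the data were examined, whose tests are not among the 35 that were adjusted. Segments numbered up to 20 took 48.5% ± 32.8 of WT TDLN, 11.7% ± 9.74 of WT tumor, 44.0% ± 22.6 of KO TDLN and 20.3% ± 14.7 of KO tumor reads. Tumor minus TDLN over both genotypes was -30.2 points (exact p = 0.035). With the TRAJ7 frame as deposited, which was repaired after the values were seen, the shares were 20.5% ± 11.5, 9.57% ± 6.05, 43.6% ± 22.8 and 12.4% ± 10.7 and the difference was -21.1 (exact p = 0.025). It was -23.5 with clonotypes shared between mice left out (exact p = 0.11), and with single libraries left out it ranged from -37.8 to -21.5 (the latter without WT TDLN 4), with exact p from 0.015 to 0.08. Segments numbered 21 to 40 took 14.9% ± 4.70, 72.7% ± 12.8, 34.3% ± 17.2 and 33.1% ± 24.3 in the same order. Single clonotypes weigh heavily here: TRAJ22 took 86.9% of WT tumor 2, where 1 TRAJ22 clonotype took 85.4%. TRAJ30 took 42.5% of WT tumor 3, where 1 TRAJ30 clonotype took 40.2%. The sets were not computed with the largest clonotype left out. KO minus WT was -39.6 points in tumor (exact p = 0.1, the smallest possible) and 19.5 points in TDLN (exact p = 0.2). With single libraries left out these ranged from -53.3 to -30.2 in tumor and from 10.6 (without KO TDLN 1) to 27.8 (without KO TDLN 2) in TDLN. Tumor minus TDLN was 57.9 points in WT (exact p = 0.1), -1.24 in KO (exact p = 0.9) and 28.3 over both (exact p = 0.065). With shared clonotypes left out, KO minus WT in tumor was -16.9 (exact p = 0.5). Tumor minus TDLN was then 29.9 in WT (exact p = 0.1) and 13.5 over both genotypes (exact p = 0.26). With the TRAJ7 frame as deposited KO minus WT in TDLN was 1.40 (exact p = 1). Segments numbered 41 to 61 took 36.7% ± 32.9, 15.6% ± 12.8, 21.7% ± 17.6 and 46.6% ± 18.7, with KO minus WT in tumor at 31.0 points (exact p = 0.2; 13.6 with shared clonotypes left out).

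The largest TRA clonotype took from 12.7% (WT TDLN 3, 95% Wilson interval 12.4% to 13.0%) to 85.4% (WT tumor 2, interval 85.1% to 85.6%) of productive reads. In WT TDLN the leading clonotypes were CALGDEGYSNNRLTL (77.5% of WT TDLN 4), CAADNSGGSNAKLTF (44.8% of WT TDLN 1) and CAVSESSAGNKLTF (12.7% of WT TDLN 3). In WT tumor they were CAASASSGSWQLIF (85.4% of WT tumor 2), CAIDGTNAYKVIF (40.2% of WT tumor 3) and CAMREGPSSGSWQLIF (20.9% of WT tumor 4). In KO TDLN they were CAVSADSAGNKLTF (35.0% of KO TDLN 2), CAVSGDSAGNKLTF (25.7% of KO TDLN 1) and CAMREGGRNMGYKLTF (20.99% of KO TDLN 2). In KO tumor they were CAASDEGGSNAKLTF (36.7% of KO tumor 2), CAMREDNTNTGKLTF (15.8% of KO tumor 2) and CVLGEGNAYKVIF (17.3% of KO tumor 1). The leading TRB sequences were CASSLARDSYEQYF (57.1% of WT tumor 2), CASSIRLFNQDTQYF (46.7% of WT tumor 3) and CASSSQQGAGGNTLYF (43.0% of WT tumor 4) in WT tumor, and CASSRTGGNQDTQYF (40.7% of KO tumor 2), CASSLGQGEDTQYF (18.8% of KO tumor 2) and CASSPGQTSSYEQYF (28.1% of KO tumor 1) in KO tumor.

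By library letter, 4132 TRA sequences were found under 1 letter, 363 under 2, 61 under 3, 23 under 4, 5 under 5 and 2 under 6. The 2 TRA sequences found in 6 were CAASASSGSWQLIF and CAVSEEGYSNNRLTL. The TRA sequences found next most widely were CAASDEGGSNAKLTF, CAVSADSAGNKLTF, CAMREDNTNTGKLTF, GTYNQGKLIF and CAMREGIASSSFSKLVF, each in 5, and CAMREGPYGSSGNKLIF, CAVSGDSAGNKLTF and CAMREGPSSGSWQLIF, each in 4. Over the 8 libraries with TRB entries, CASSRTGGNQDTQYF and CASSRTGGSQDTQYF were each found under 6 letters, and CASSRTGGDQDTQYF, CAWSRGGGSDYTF, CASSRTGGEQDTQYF and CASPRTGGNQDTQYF under 5. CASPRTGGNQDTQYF stayed under 0.1% in every library, with at most 0.0227% (KO tumor 2). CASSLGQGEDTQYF, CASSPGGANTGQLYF, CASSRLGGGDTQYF and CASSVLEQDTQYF were found in 4. A single read counts as found here, and libraries of different letters shared many clonotypes. How many mice these letters stand for was not established.

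Sequences CASSRTGGxQDTQYF, with any amino acid at x, were taken as 1 family after their values were seen. The family took 7.58% of TRB reads in WT tumor 2 (95% Wilson interval 7.36% to 7.81%), 18.4% in WT tumor 3 (18.2% to 18.7%) and 20.4% in WT tumor 4 (20.2% to 20.6%). It took 4.12% in KO tumor 1 (3.99% to 4.26%), 40.8% in KO tumor 2 (40.5% to 41.1%) and 14.2% in KO tumor 3 (14.03% to 14.4%). Means were 15.5% ± 6.89 in WT and 19.7% ± 18.9 in KO tumor (exact two-sided p = 0.9, n = 3 each). Of the TDLN libraries with TRB entries, WT TDLN 4 had 0.842% (0.733% to 0.966%) and KO TDLN 3 had 0.0214% (0.0137% to 0.0334%).

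**Figure D2:**
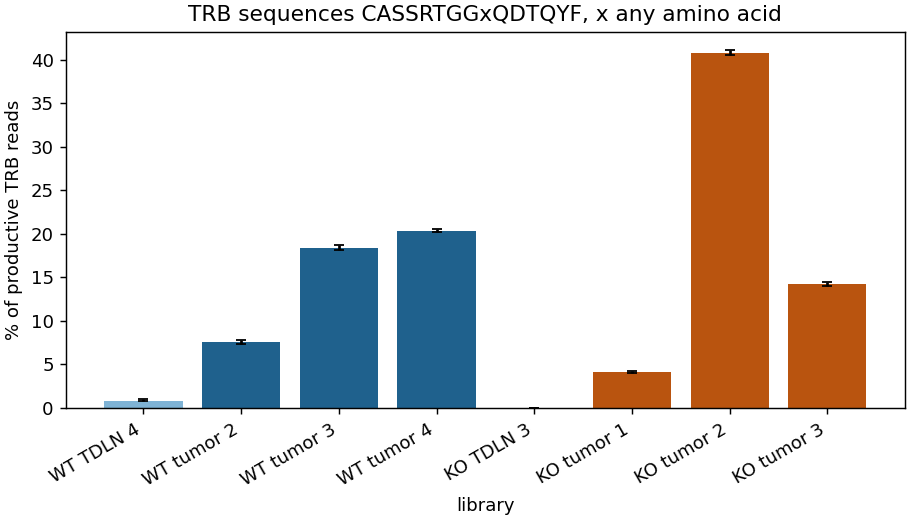
Percent of productive TRB reads in the family CASSRTGGxQDTQYF in the 8 libraries with TRB entries, coloured by group, with 95% Wilson intervals. The 6 tumor libraries lie between 4.12% and 40.8%.

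Libraries of the same number were compared to ask whether tumor clones were also in the draining node. The 6 pairs of TDLN and tumor libraries that share a library letter had a mean TRA overlap of 0.000286, and the highest was 0.000798. The 12 TDLN and tumor pairs of different number within a genotype had a mean of 0.00904 (difference -0.00875, exact one-sided permutation p = 0.694), and all 30 pairs of different letter had a mean of 0.0384. Leaving out single pair numbers gave differences from -0.0134 to -0.000267, since WT TDLN 1 with WT tumor 4 (0.103) makes up most of the mean of 0.00904. These values are by nucleotide clonotypes. By CDR3 amino acids alone the same-letter pair KO TDLN 1 with KO tumor 1 reached 0.0522 (4.38e-05 by clonotypes). The next highest same-letter pair then had 0.000869, and WT TDLN 1 with WT tumor 4 had 0.0880. KO minus WT of same-letter overlap by clonotypes was -1.47e-05 (exact two-sided p = 0.9, n = 3 each). The TRB overlap differed between same and different numbers by -0.594 points (exact one-sided p = 0.556), and between KO and WT by 0.871 points (exact two-sided p = 0.2).

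Of all 66 pairs of libraries, 6 had an overlap of TRA nucleotide clonotypes over 0.1, and each joined libraries of different letters. They were KO tumor 2 with KO tumor 3 (0.707), WT tumor 3 with KO TDLN 3 (0.410), WT TDLN 3 with KO tumor 3 (0.398), WT tumor 4 with KO tumor 1 (0.203), WT tumor 2 with KO TDLN 1 (0.110) and WT TDLN 1 with WT tumor 4 (0.103). By CDR3 amino acids alone WT tumor 4 with KO TDLN 1 also passed 0.1, at 0.228 (0.000225 by clonotypes). WT TDLN 1 with WT tumor 4 then fell to 0.0880. The TRB matrix of the authors lists 639 shared sequences for KO tumor 2 with KO tumor 3, against a median of 52 over all pairs. Clonotypes at 1% or more of KO TDLN 3 made up 87.2% of WT tumor 3 reads (95% Wilson interval 86.9% to 87.5%, next highest TDLN library 2.75%). Those of WT TDLN 1 made up 62.7% of WT tumor 4 (62.3% to 63.04%, next 0.0290%) and those of WT TDLN 3 made up 41.02% of KO tumor 3 (40.6% to 41.5%, next 0.0697%). For WT tumor 2 this share was 91.1% in KO TDLN 1 (90.95% to 91.3%) and also 85.4% in KO TDLN 2, so it does not single out one library. For KO tumor 1 the highest share was 13.2%, in WT TDLN 1, and for KO tumor 2 it was 0.117%, in KO TDLN 1. Libraries labelled with different genotypes thus held the same clonotypes, and the comparisons of KO with WT rest on the labels as given. The p values and SDs over libraries, also those of tumor against TDLN, treat these libraries as independent and hold only under that assumption. Within groups, pairs of KO libraries shared more of their TRA sequences than pairs of WT libraries, by 2.26 points of the Jaccard index, and more of their TRB sequences, by 2.82 points. Without the pair of KO tumor 2 and KO tumor 3 these differences were 0.355 and 0.328 points. They were not tested, since pairs share libraries.

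**Figure D3:**
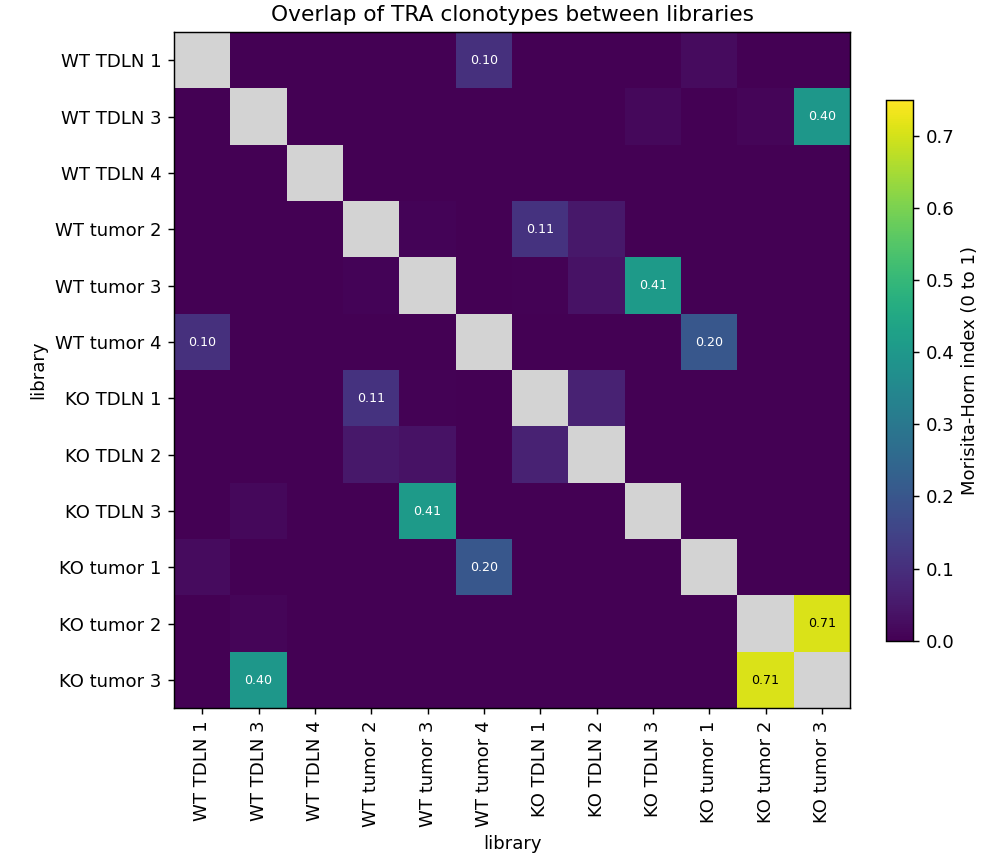
Morisita-Horn overlap of TRA clonotypes between the 12 libraries (0 is none, 1 is identical shares, diagonal in grey). Values over 0.1 are printed, and the highest is 0.71 for KO tumor 2 and KO tumor 3.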

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

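All tests of explanations given here were chosen after the patterns were seen. The bounds that sort their values were written after the values were seen, and other bounds could decide values left undecided here. Rearrangements that make no receptor, which enter none of the comparisons, held 14.5% of TRA reads, and they were used to weigh the sharing of clonotypes between libraries. Groups of 3 libraries are too small for a test of outlying libraries.

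The 6 pairs of libraries with an overlap over 0.1 joined different library letters, and 4 of them joined a TDLN with a tumor library. Receptors that arise in different mice and are selected there would share productive rearrangements but not the silent rearrangement of the other allele. In WT TDLN 3 and KO tumor 3 the overlap of rearrangements that make no receptor was 0.710, in KO TDLN 3 and WT tumor 3 it was 0.639, and in KO tumor 2 and KO tumor 3 it was 0.370. These values argue against independent selection in those 3 pairs. In WT TDLN 1 and WT tumor 4 (0.0791), KO TDLN 1 and WT tumor 2 (0.0432) and WT tumor 4 and KO tumor 1 (0.0820) the overlap lay between the bounds set for the test, which decides neither way. The highest value among the other 60 pairs was 0.0486, and their median was 1.92e-08. Of these undecided pairs only KO TDLN 1 and WT tumor 2 did not exceed that highest value. In the TDLN and tumor pairs 46 of 47 shared amino acid sequences at 0.1% or more had the same leading nucleotide sequence, and in the tumor pairs 19 of 23 did. In the undecided pairs it was 13 of 13, 4 of 4 and 7 of 9, in the order named above. The 6 pairs were picked by overlap of nucleotide clonotypes, which favours shared nucleotide sequences, so these counts weigh on neither side. WT tumor 4 with KO TDLN 1, at 0.228 by CDR3 amino acids but 0.000225 by clonotypes, was not among the 6.

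Carry-over of material would keep the proportions of the carried clones, so the SD of the log10 ratio of their shares, in the direction where it is smaller, would be low. It covers only clones found in both libraries, so clones that were not carried are left out. Of clones at 1% or more, 15 of 20 of WT TDLN 3 were in KO tumor 3, and 7 of 13 of WT tumor 4 were in KO tumor 1. The SD was 0.267 for WT TDLN 3 and KO tumor 3 and 0.207, from 5 clones of KO tumor 1, for WT tumor 4 and KO tumor 1. Carry-over stays a candidate explanation in these pairs, within that limit of the SD. The SD was 0.705 for WT TDLN 1 and WT tumor 4 and 0.653 for KO TDLN 3 and WT tumor 3, which argues against carry-over as the whole cause in those pairs. It was 0.343 for KO tumor 2 and KO tumor 3 and 0.458, from 4 clones, for KO TDLN 1 and WT tumor 2, which decides neither way. Carry-over was examined only in the 6 pairs over 0.1. By any read, other pairs shared much too. Clonotypes of KO TDLN 3 held 97.5% of WT tumor 2 reads (overlap 0.00233), and those of KO TDLN 2 held 89.7% of WT tumor 4 reads (overlap 0.000984). The cause of this sharing was not tested. An exchange of the libraries numbered 3 between the genotypes may account for the crossed pairs of that number. The overlap of the 2 crossed pairs averaged 0.404 and that of the pairs as labelled 0.000714. An exchange of the TDLN libraries and one of the tumor libraries would give the same values. Neither would account for the other pairs over 0.1, among them KO tumor 2 with KO tumor 3 (0.707). A mouse whose node and tumor carry different numbers stays open too, as the labels do not say that a number marks a mouse. No library was moved to another group.

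TRAJ7 was called out of frame in 94.7% of its reads as deposited, and TRAJ34 in 80.5%. Of the out-of-frame TRAJ7 entries, 98.0% had a length of 2 more than a multiple of 3, as a CDR3 end placed 1 base short would give. Among out-of-frame entries of other TRAJ segments 53.2% fell in that class, which argues against rearrangements that make no receptor as the main source. In the table of all chains, 141 TRAJ7 entries end 1 base later, and 10.6% of them are out of frame. The deposited frame may thus hide TRAJ7 clones, such as the one with 77.5% of WT TDLN 4, a candidate explanation from the 98.0% above. No biological explanation by genotype or tissue was tested for this pattern.

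Fewer TRA clonotypes were found in tumor than in TDLN. Depth as the whole cause is argued against by the exact permutation p of 0.01 at equal depth, and sequence errors around abundant clones by the exact permutation p of 0.005 with rare neighbours merged, the smallest possible. Runs noted as timed out were TDLN libraries only, so note and tissue are partly confounded. Among libraries with no such note, the 6 tumor libraries had -95.9 clonotypes relative to the 2 TDLN libraries (exact two-sided permutation p = 0.214, 28 assignments), which leaves this explanation open. The difference did not pass the correction over 35 tests, and a difference between the tissues themselves stays open and untested.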

How the results depend on the processing

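Over 52 results and 789 alternative values, 54 tested values changed direction, 35 tested values or counts of calls fell and 17 rose past the threshold or by over 1.5 times, and 8 untested values moved by more than the spread between libraries. The other 675 stayed within these bounds. Of the untested values 3 changed sign, 2 of them within 1 SD. The causes were not tested unless given. Chosen after the values were seen were the alternatives named so in the processing part. Nearly all reversals concern differences that passed no threshold.

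The difference in TRA clonotypes over both genotypes, -145.1, ranged from -169.2 to -125.5 with single libraries left out (exact p from 0.005 to 0.015). The clonotype number as listed gave -242.7 (exact p = 0.085).

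Other indices: the Gini coefficient gave 0.000428 for TRA clonality KO minus WT in TDLN and 0.00319 for tumor minus TDLN in KO, and inverse Simpson, which is higher when shares are more even, gave -0.438 for the former. Leaving out clonotypes under 0.01% gave -0.00402 for TRA clonality tumor minus TDLN in both genotypes. Leaving out single counts gave -3.24 clonotypes and the number as listed -72.0 for KO minus WT in tumor. For the difference between genotypes, -35.1, the listed number gave -190.7 and the TRAJ7 frame as deposited 0.521.
The top 1 share gave, for TRA, -19.1 points KO minus WT in TDLN, -0.943 tumor minus TDLN in KO and -4.75 for the difference between genotypes. For TRB it gave -12.4 KO minus WT in TDLN, -4.73 tumor minus TDLN in WT and -15.65 in both genotypes. The top 100 TRA share gave -1.01 KO minus WT in TDLN, 1.68 tumor minus TDLN in both genotypes (exact p = 0.01) and 0.742 for the difference between genotypes. The top 5 TRB share gave -4.42 in both genotypes and -27.6 for the difference between genotypes. TRA entries as deposited gave -5.96 for the top 10 share tumor minus TDLN in KO.
Each clonotype counted once gave TRA lengths of 0.0400 KO minus WT in TDLN, -0.0851 in tumor and 0.335 tumor minus TDLN in WT.
The TRAJ7 frame as deposited gave 0.102 for TRA clonality and 0.126 for TRA length KO minus WT in TDLN, and -0.282 (clonality) and -27.1 (top 10 share) for the difference between genotypes.
Leaving out clonotypes shared between mice gave TRA clonality of -0.0632 tumor minus TDLN in WT, -0.0672 in both genotypes and -0.00819 for the difference between genotypes, and top 10 shares of -0.693 KO minus WT in TDLN and -2.31 for the difference between genotypes.
Leaving out WT tumor 3 and KO tumor 3 gave 0.0106 for TRA clonality tumor minus TDLN in KO and -75.2 TRB sequences in both genotypes.
For TRA overlap KO minus WT, the share of tumor reads gave 0.531 and amino acids alone 0.0174. By amino acids KO TDLN 1 with KO tumor 1 had an overlap of 0.0522.

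With single libraries left out, signs changed within these ranges. TRA clonality: -0.137 to 0.0184 KO minus WT in TDLN, -0.0491 to 0.0116 tumor minus TDLN in KO. TRA top 10 share: -6.87 to 8.55 KO minus WT in TDLN and -4.17 to 6.49 tumor minus TDLN in KO. TRB sequences: -145 to 439 KO minus WT in TDLN, -389.5 to 86.0 tumor minus TDLN in WT, -109.8 to 550.3 in KO and -142.6 to 187.5 in both genotypes. TRB top 10 share: -7.72 to 7.53 KO minus WT in TDLN and -1.86 to 5.77 tumor minus TDLN in both genotypes. TRA clonotypes: -74.4 to 13.07 for the difference between genotypes. Overlap: -0.000190 to 0.000237 for TRA KO minus WT and -1.25 to 0.0508 for TRB same minus different number. Without a change of sign, the TRA top 10 share tumor minus TDLN in both genotypes ranged from 4.20 to 11.9, and without KO tumor 3 it was 11.4 (exact p = 0.035).

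Called segments, TRAV: KO minus WT gave 1 in TDLN and 2 in tumor with DESeq2, and 0 to 1 in tumor with single libraries left out. Tumor minus TDLN in WT gave 3 with DESeq2 and 0 with TMM, limma with 0.1% or 1% added, each clonotype once, only the 2 groups compared, the dominant clone left out, entries as deposited, the TRAJ7 frame as deposited, shared clonotypes left out, or WT tumor 3 and KO tumor 3 left out, and 0 to 1 with single libraries left out. In KO it gave 8 with DESeq2, 4 with limma (0.1%), 1 with each clonotype once and 1 with only the 2 groups. In both genotypes it gave 2 with TMM, 0 with limma (both), 4 with each clonotype once, 4 with entries as deposited, 1 without shared clonotypes, 23 without WT tumor 3 and KO tumor 3, and 3 to 14 with single libraries left out (3 without WT tumor 2, 4 without KO tumor 2, 5 without KO tumor 1). DESeq2 called 10 there, 4 higher and 6 lower.
TRAJ: KO minus WT in tumor gave 3 with DESeq2 and 1 with limma (0.1%). Tumor minus TDLN gave 5 with DESeq2 and 0 to 2 with single libraries left out in WT, and 7 with DESeq2 in KO. In both genotypes it gave 2 and 0 with limma (0.1% and 1% added), 5 with each clonotype once, 15 without WT tumor 3 and KO tumor 3, and 5 to 12 with single libraries left out (5 without KO TDLN 2 or KO tumor 1).

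The labels do not say that a number marks a mouse, so the numbers were not taken as pairs. Deviations from the group means correlated over the 5 same-numbered pairs at 0.0613, -0.264, -0.0718, -0.000675 and -0.0135, and no library correlated best with its own number. With the number as a block, TRA clonotypes over both genotypes gave -133.3 (exact p = 0.125), and -145.1 with the letter A pair (exact p = 0.0625). The block gave 12.5 TRB sequences tumor minus TDLN in WT, -0.400 for the TRB top 10 share in both genotypes, and 0 called TRAV segments in WT, 0 TRAV in both genotypes and 0 TRAJ in both genotypes.

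Other splits of the libraries were counted for called segments. Over both genotypes, 1 of 100 splits, the real one, called as many TRAV segments (12, highest other 4), and 1 of 100 as many TRAJ segments (8, highest other 2). Splits treat the libraries as independent, while many pairs share clonotypes, 6 of them with an overlap over 0.1, so this share holds only under that assumption. For comparisons of 3 against 3, the 10 splits are too few for a share under 0.05. There the real and highest other counts were 0 and 0 for TRAV KO minus WT in TDLN and tumor and tumor minus TDLN in KO (10 of 10 splits each), and 1 and 1 in WT (4 of 10). For TRAJ they were 0 and 0 (10 of 10) except 0 and 8 for KO minus WT in tumor. That split set WT tumor 2, WT tumor 4 and KO tumor 1 against WT tumor 3, KO tumor 2 and KO tumor 3. It keeps together 2 pairs that share clonotypes (WT tumor 4 with KO tumor 1, and KO tumor 2 with KO tumor 3), a structure of the samples whose part in the 8 calls was not tested.

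Not run were TRBV and TRBJ comparisons, and TRB clonality, length and alternatives that need entries for all libraries. Depth limits rare clonotypes: the smallest library, WT TDLN 4, held 15828 productive TRA reads.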

Other observations

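The tests in this part were chosen after the values were seen. Of 341 families of TRB sequences with 1 free position, built around sequences at 1% or more of a tumor library, 1 reached 1% in 6 of 6 tumor libraries, CASSRTGGxQDTQYF. The highest among the others was 4 of 6, in 6 families that each hold a sequence of this family. The 310 families that hold none reached at most 3. A hypothesis is that separate rearrangements encode this chain in different mice. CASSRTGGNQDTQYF reached 1% in 4 libraries, through 3 different leading nucleotide sequences, so separate rearrangements that encode one TRB chain may be present, with the value 3 as the test. KO tumor 2 and KO tumor 3 held the same nucleotide sequence and count as 1. WT tumor 4 and KO tumor 1 also shared the nucleotide sequence of their leading member, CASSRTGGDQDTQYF. The table holds TRB entries of only 2 of the 6 TDLN libraries, so whether the family is more abundant in tumor than in TDLN was not tested.

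Of the productive TRA reads of KO tumor 3, 94.6% were in clonotypes at 0.1% or more of KO tumor 2 or WT TDLN 3. By any read, 95.4% were in clonotypes of either library and 2.07% in clonotypes of both.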
